A study of Arabidopsis thaliana with 6 samples.

How the data were processed

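Floral organ abscission in Arabidopsis thaliana takes place between neighbouring cell layers at the base of the floral organs. The series holds 6 polyA RNA-seq libraries of cells from this zone, 3 of residuum cells (REC, the cells that stay on the receptacle) and 3 of secession cells (SEC, the cells that leave with the shed organs). All libraries came from flowers at stage 16 of plants with the reporter proQRT2::nlsGFP-GUS, in which the promoter of the polygalacturonase gene QRT2 drives a nuclear green fluorescent protein. The series' design text says that fluorescence was used to sort the cells. Per the labels' protocols, RNA was taken from protoplasts, cDNA was amplified with the SMART-Seq low-input kit, and libraries were built with the TruSeq RNA kit. The labels number the libraries within each group but do not say that they came from separate plants or sorts, so p-values measure only the spread between these samples, which may be technical.

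The deposited table holds raw counts of reads per gene for the 6 libraries, with no normalization. Per the submitters' processing notes, the tools were bcl2fastq 1.8.4, FastQC 0.11.2, Trimmomatic 0.32.3, TopHat2 2.0.9, Picard 1.119, HTSeq 0.6.1 and DESeq2, on the genome build TAIR10. The annotation release, the strand setting of the counter and any step of duplicate removal are not given in the sources used here. The table lists 33602 genes and 5 summary rows of the counter, which were kept out of library sizes and tests. Reads assigned to no feature were 42.78% to 45.91% of all records per library, reads at more than 1 site 6.86% to 11.83%, and ambiguous reads 0.41% to 0.54%. Total counts over genes ranged from 13222538 to 17192864 per library. At this depth 3 counts over a whole group correspond to 0.058 CPM (counts scaled to a common library size) in REC and 0.0818 CPM in SEC. These floors, and the intervals given for ratios, cover counting error only, since amplified reads are not independent molecules.

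Coordinates are those of the deposited table on TAIR10, written here with starts counted from 1: 14406 gene starts equal those of the RefSeq annotation of TAIR10.1 when the table's starts are read as counted from 0, against 134 when read as counted from 1. Of the genes in the table, 32835 matched that annotation by locus. It supplied strand, product names, symbols, gene types, exons and the gene spans used to find overlaps. Start and end were the same in both for 10315 genes, so overlaps in the annotation that was counted may differ. The RefSeq annotation places 6175 genes over a gene on the opposite strand. Without a stated strand setting, the reads of such genes and of their partners cannot be told apart with certainty. Reads at more than 1 site were left out of gene counts, so levels of genes with near-identical copies are uncertain as well.

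Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes with low counts were removed by filterByExpr with the group, which left 17246 genes. Libraries were scaled with TMM factors. SEC was compared with REC by edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment, with an adjusted p threshold of 0.05, and fold changes are SEC minus REC on the log2 scale. The standard error of a log2 fold change was taken as its size divided by the square root of F. Levels are TMM-normalised CPM, as the mean ± SD of 3 libraries. Where a group had 0 counts over its 3 libraries, the fold is a lower bound against 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with its exact 95% counting interval.

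Before the data were examined, 29 gene lists of 464 entries (pathways, gene families and markers of other cell types) and 7 families defined by product names were fixed, and the locus of every entry was in the table. Lists with at least 3 tested members were compared with all other genes by limma's camera on voom values with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 32 lists. Also fixed then was the rule for named genes. It takes QRT2, IDA, HAE, HSL2, ADPG1 and ADPG2, the 6 genes with the largest fold change in each direction (adjusted p under 0.05, mean of at least 10 CPM, no overlap between the groups), and the members with the smallest adjusted p of each list, up to 3 for pathway lists and up to 2 for markers of other cell types and of stress. It named 84 genes. Members on the less frequent side of a list, where that side had 1 to 3 called members outside the rule, were added after their values were seen. Alternatives fixed at the same time were RLE and upper-quartile scaling, no filter, a filter of at least 10 CPM in 3 libraries, DESeq2, limma voom with quality weights, a replicate block, organelle genes left out, an adjusted p threshold of 0.01 and each library left out in turn, and for lists also an estimated correlation and the fry test. Scaling by library size alone, leaving out genes that overlap an opposite-strand gene, and families by symbol stem were chosen after seeing the data.

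The steps were tested on simulated counts with 16935 genes tested and 100 genes changed at each fold size. edgeR found 7% of the 2-fold and 62% of the 4-fold changes with 0 false among 69 calls. DESeq2 found 14% and 64% with 17 false among 95 calls, and limma voom 6% and 55% with 0 false among 61 calls. Camera found the 1 changed list among 31 with 0 false calls. The simulation changed few genes, evenly up and down, whereas 60.8% of genes were called in the data. Its recovery rates therefore do not carry over to the real comparison. Genes were drawn independently of each other, so camera was not tested on correlated genes. Replicate libraries of a group differed by more than counting noise, with a chi-square per degree of freedom of at least 27.8. Separately amplified libraries of the same RNA can differ by more than counting noise too, so this does not tell whether any library repeats another. Each library was counted as a separate sample.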

Results

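The data were read counts per gene from protoplasts of the abscission zone of Arabidopsis thaliana flowers at stage 16, in 3 REC libraries and 3 SEC libraries. Total counts over genes were 13721261, 14659524 and 14464710 in REC replicates 1, 2 and 3. They were 13845818, 17192864 and 13222538 in SEC replicates 1, 2 and 3. Coordinates below are on TAIR10. Between 17644 and 19665 genes had at least 1 read in a library. The series title concerns a lignin structure in abscission, and the comparison of SEC with REC asks how the cells on either side of the separation plane differ in expression.

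REC and SEC cells differed in most of the genes tested. Of 17246 genes, 4978 were higher in SEC and 5499 were lower (edgeR quasi-likelihood test, adjusted p under 0.05), which is 60.8% of the genes tested. Changes of at least 2-fold made up 4424 of the higher and 5135 of the lower genes. The libraries of the groups did not overlap in 71.5% of genes, where chance gives 10%. Correlations of log2 CPM across genes were 0.886 to 0.914 between REC libraries, 0.934 to 0.957 between SEC libraries and 0.448 to 0.563 between the groups. REC replicate 3 lay nearest to SEC among the REC libraries. The balance of higher and lower calls depended on the scaling: 47.5% of calls were higher in SEC with TMM factors and 33.7% with library size alone, with 3521 higher and 6925 lower. Library size alone moved the median log2 fold change of all genes from -0.07 to -0.61, and upper-quartile scaling moved it to -0.31, so fold changes below are relative to the TMM scale.

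**Figure D1:**
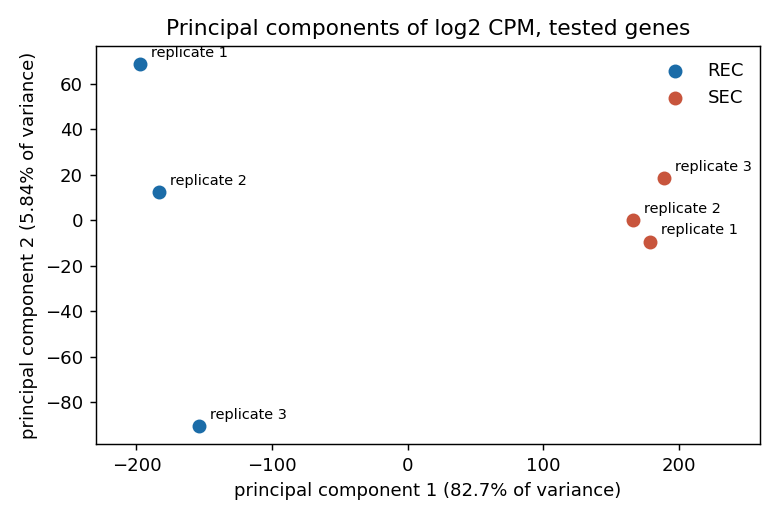
First and second principal components of log2 CPM over the 17246 tested genes, in arbitrary units, with each point a library coloured by group. Component 1, with 82.7% of the variance, parted REC from SEC, and component 2, with 5.84%, spread the REC libraries.

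The genes with the largest fold changes were present in one group and at 0 counts, or close to it, in the other. Higher in SEC was AT1G50590 (chromosome 1, 18732378 to 18734053, minus strand) at 122 ± 27.9 CPM (SD, n = 3) and at least 2100-fold above REC. DOX1 (AT3G01420), a fatty acid dioxygenase gene, was at least 1740-fold higher, CTL2 (AT3G16920), a chitinase-like gene, at least 1650-fold and AT5G35110 at least 1270-fold. CYP71A12 (AT2G30750), a cytochrome P450 gene of camalexin synthesis, was at least 1150-fold higher and the laccase gene LAC15 at least 1140-fold higher. Lower in SEC was the aldehyde dehydrogenase gene ALDH3F1 (AT4G36250; chromosome 4, 17150869 to 17153578, plus strand), at 953 ± 83.8 CPM in REC (SD, n = 3) and at least 11700-fold lower in SEC. CAD9 (AT4G39330), of the cinnamyl alcohol dehydrogenase family, was at least 6330-fold lower. The fatty acyl reductase gene CER4 (AT4G33790) was at least 5860-fold lower, the glycine-rich protein gene GRP-5 (AT3G20470) at least 4090-fold and the glycerol-3-phosphate acyltransferase gene GPAT4 (AT1G01610) at least 2130-fold. The lipid transfer protein gene LTP3 (AT5G59320) had 63784 counts over the REC libraries and 1 over the SEC libraries, a ratio of 45200 (95% counting interval 8120 to 1790000). Its single SEC count came from replicate 1, and without that library SEC had 0 counts and the gene was at least 10500-fold lower. These 12 genes passed the edgeR test, with adjusted p between 1.17e-05 and 0.000257.

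QRT2, IDA, HAE, ADPG1 and ADPG2 were higher in SEC, and HSL2 was lower. QRT2 (AT3G07970; chromosome 3, 2541006 to 2543432, plus strand), whose promoter drove the reporter, was at 41.8 ± 32.7 CPM in REC and 1720 ± 151 CPM in SEC (SD, n = 3), a log2 fold change of 5.36 ± 0.57 (SE; edgeR adjusted p = 0.000123). IDA (AT1G68765; chromosome 1, 25829952 to 25830487, minus strand), which encodes the peptide that triggers organ shedding, rose from 2.17 ± 3.47 to 395 ± 87.6 CPM (log2 7.51 ± 1.31, SE; edgeR adjusted p = 0.00152). Its receptors went opposite ways. HAE (AT4G28490; chromosome 4, 14077857 to 14081171, plus strand) was higher in SEC, at 1310 ± 273 against 202 ± 132 CPM (log2 2.70 ± 0.45, SE; edgeR adjusted p = 0.00115). HSL2 (AT5G65710; chromosome 5, 26292372 to 26295440, plus strand) was lower, at 16.7 ± 4.9 against 55.8 ± 13.8 CPM (log2 -1.74 ± 0.32, SE; edgeR adjusted p = 0.00207). The polygalacturonase genes ADPG1 (AT3G57510; chromosome 3, 21283338 to 21285941, minus strand) and ADPG2 (AT2G41850; chromosome 2, 17461655 to 17464161, minus strand) rose by log2 9.38 ± 0.87 and 8.82 ± 1.44 (SE), to 82.9 ± 35.9 and 4570 ± 951 CPM, with edgeR adjusted p of 6.56e-05 and 0.00108. The size of several of these changes rested on single REC libraries. Without REC replicate 3 the log2 fold changes were 6.23 for QRT2, 11.10 for IDA, 3.39 for HAE and 11.86 for ADPG2, and ADPG1, then with 0 counts in REC, was at least 964-fold higher in SEC. Without REC replicate 1 that of IDA was 6.92, and without REC replicate 2 that of ADPG1 was 8.79.

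Of the 28 tested abscission regulators, 15 were higher in SEC, 6 were lower and 7 were not called, and the list as a whole did not pass (camera adjusted p = 0.127). The transcription factor genes DOF4.7 (AT4G38000) and AGL18 (AT3G57390) were higher in SEC, DOF4.7 with 0 counts in REC and at least 643-fold above it, and AGL18 by log2 2.14 ± 0.24 (SE; edgeR adjusted p = 0.000179). The homeobox gene KNAT1 (AT4G08150) fell from 204 ± 39.5 to 13.5 ± 2.46 CPM (log2 -3.92 ± 0.26, SE; edgeR adjusted p = 1.8e-05). The list holds genes that restrain abscission as well as genes that promote it, and members were not sorted by role. Its counts of higher and lower genes therefore do not show whether shedding is activated. Among 5 tested polygalacturonase, pectate lyase and cellulase genes, 3 were higher in SEC and 1 was lower (camera adjusted p = 0.139). The higher ones include QRT2 and ADPG1, already described above, so this count is not a separate result. The lower one was PMR6 (AT3G54920), a pectate lyase-like gene, at 69.5 ± 21.2 CPM in REC and 2.13 ± 1.46 CPM in SEC, with a log2 fold change of -5.0 that was -5.71 without SEC replicate 2.

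Genes of lignin oxidation were higher in SEC as a list (camera adjusted p = 0.0139; adjusted p = 0.572 with an estimated correlation), while those of monomer synthesis did not pass as one. Of 17 tested monomer genes, 9 were higher in SEC, 3 lower and 5 not called (camera adjusted p = 0.122). Without SEC replicate 1 the monomer list passed (adjusted p = 0.0249, within a range of 0.0249 to 0.166 over the alternatives of camera with the preset correlation). Higher members included CAD5 (AT4G34230), a cinnamyl alcohol dehydrogenase gene, at 2060 ± 148 against 365 ± 43.7 CPM (log2 2.50 ± 0.20, SE; edgeR adjusted p = 3.69e-05), the coumaroyl hydroxylase gene CYP98A3 (AT2G40890) with log2 3.76 ± 0.39 (SE), and C4H (AT2G30490) with log2 2.2 ± 0.31 (SE). Of 31 listed laccases and lignin-linked class III peroxidases, 12 had enough counts to be tested, and 7 were higher, 1 lower and 4 not called. The untested members had 0 to 45 counts over all libraries, so the list call covers only the expressed members. LAC15 (AT5G48100; chromosome 5, 19489327 to 19492744, minus strand) and LAC7 (AT3G09220) had 0 counts in REC and stood at 66.0 ± 14.2 and 48.8 ± 10.1 CPM in SEC, with LAC7 at least 841-fold higher. PRX47 (AT4G33420) was at 168 ± 54.2 CPM in SEC and 0.177 ± 0.212 CPM in REC, and its log2 fold change of 9.84 was 9.24 without REC replicate 2. Without REC replicate 3 it had 2 counts in REC, and the ratio was 2960 (95% counting interval 819 to 24400). The whole class III peroxidase family had 15 higher and 5 lower members of 30 tested (camera adjusted p = 0.0331; adjusted p = 0.614 with an estimated correlation). It did not pass without SEC replicate 3 (adjusted p = 0.0561, within a range of 0.0055 to 0.0561 over the same kind of alternatives). Of 17 listed secondary wall genes only 5 had enough counts to be tested, and 3 were higher and 1 was lower (camera adjusted p = 0.337). IRX14 (AT4G36890), of xylan synthesis, and the lignin regulator MYB58 (AT1G16490) were higher by log2 1.77 ± 0.32 and 2.72 ± 0.53 (SE), while MYB63 (AT1G79180), a close relative of MYB58, was lower by log2 -2.41 ± 0.63 (SE) and by -3.02 without SEC replicate 3. Of 9 listed Casparian strip genes 3 could be tested. Only CASP2 (AT3G11550) was called, and it was lower in SEC, at 2.75 ± 0.772 against 32.2 ± 11.9 CPM. That list did not pass (camera adjusted p = 0.582), and its median log2 fold change, 0.14, had the opposite sign to its camera direction. The NADPH oxidase and superoxide dismutase list had 5 higher and 2 lower of 10 tested (camera adjusted p = 0.428). The NADPH oxidase genes RBOHD (AT5G47910) and RBOHF (AT1G64060) were higher by log2 3.59 ± 0.35 and 2.54 ± 0.27 (SE), and the superoxide dismutase gene FSD1 (AT4G25100) was lower, at 59.6 ± 35.8 against 1420 ± 189 CPM.

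Most of the tested cutin and wax genes were lower in SEC. Of 19 tested cutin genes, 14 were lower, 1 higher and 4 not called, with a median log2 fold change of -7.30, or -6.45 with genes at 0 counts set to their bound (camera adjusted p = 0.000437; adjusted p = 0.233 with an estimated correlation). Of 17 tested wax genes, 14 were lower, 1 higher and 2 not called, with a median of -7.32 (camera adjusted p = 0.000426; adjusted p = 0.233 with an estimated correlation). The higher ones, chosen after their values were seen, were GPAT6 (AT2G38110) of the cutin list, at 1910 ± 360 against 771 ± 381 CPM, and KCS1 (AT1G01120) of the wax list, at 123 ± 60.3 against 17.6 ± 5.64 CPM. The call of GPAT6 (edgeR adjusted p = 0.0123) ended with library size alone (adjusted p = 0.0788). The transporter gene ABCG11 (AT1G17840), which exports cuticular lipids, fell from 245 ± 26.4 to 0.577 ± 0.233 CPM (log2 -8.67 ± 0.34, SE; edgeR adjusted p = 1.17e-05), and the fatty acid hydroxylase gene CYP86A2 (AT4G00360) by a log2 fold change of -7.30 ± 0.50 (SE). CER3 (AT5G57800; chromosome 5, 23420209 to 23424052, plus strand), of alkane synthesis, was at 1190 ± 197 CPM in REC and 0.166 ± 0.216 CPM in SEC, with a log2 fold change of -12.57. Without SEC replicate 2 it had 1 count in SEC, and the ratio was 27100 (95% counting interval 4870 to 1070000). The alkane-forming gene CER1 (AT1G02205) and its neighbour CER1L1 (AT1G02190) had log2 fold changes of -7.47 ± 0.38 and -7.15 ± 0.31 (SE). Of 7 tested cuticle transcription factors 3 were lower and 1 was higher, and the list did not pass (camera adjusted p = 0.307). The 3 lower ones were HDG1 (AT3G61150), MYB94 (AT3G47600) and MYB96 (AT5G62470), with log2 fold changes of -4.84, -5.11 and -7.12, those of MYB94 and MYB96 being -5.70 and -7.75 without SEC replicate 3. Of 9 tested genes of epidermal identity, 3 were lower and 6 were not called (camera adjusted p = 0.337). These were ANL2 (AT4G00730) at 13.3 ± 4.48 CPM in REC and 0.137 ± 0.237 in SEC, PDF2 (AT4G04890) at 5.9 ± 1.41 and 0.148 ± 0.256, and PDF1 (AT2G42840), with 0 counts in SEC and at least 25.6-fold lower. The SEC counts of ANL2 came from replicate 2 and those of PDF2 from replicate 1, and their log2 fold changes were -6.36 and -5.29. Without those libraries SEC had 0 counts, and ANL2 was at least 101-fold and PDF2 at least 50.3-fold lower.

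Among suberin genes, which act on related lipids, more members were higher than lower. Of 12 listed genes 8 could be tested, and the listed CYP86A1 and CYP86B1 had 0 counts in every library. Of the 8, 5 were higher in SEC, 1 was lower and 2 were not called, and the list did not pass (camera adjusted p = 0.0746). It passed without REC replicate 2 (adjusted p = 0.0386), REC replicate 3 (0.0394), SEC replicate 1 (0.0314) or SEC replicate 2 (0.0425), with no filter (0.0188) and with library size alone (0.0244), within a range of 0.0188 to 0.121 over the same kind of alternatives. GPAT5 (AT3G11430; chromosome 3, 3595765 to 3597952, plus strand), an acyltransferase gene of suberin synthesis, rose from 1.69 ± 2.07 to 767 ± 323 CPM, with a log2 fold change of 8.82 ± 1.19 (SE; edgeR adjusted p = 0.000404) that was 8.22 without REC replicate 2 and 10.50 without REC replicate 3. The fatty acyl reductase genes FAR4 (AT3G44540) and FAR5 (AT3G44550) were abundant in both groups and rose from 648 ± 113 to 2640 ± 312 CPM and from 1590 ± 250 to 4680 ± 520 CPM. Their relative FAR1 (AT5G22500), the lower member of the list and chosen after its values were seen, fell from 2390 ± 231 to 322 ± 227 CPM, with a log2 fold change of -2.89 ± 0.49 (SE; edgeR adjusted p = 0.00125) that was -3.62 without SEC replicate 3.

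**Figure D2:**
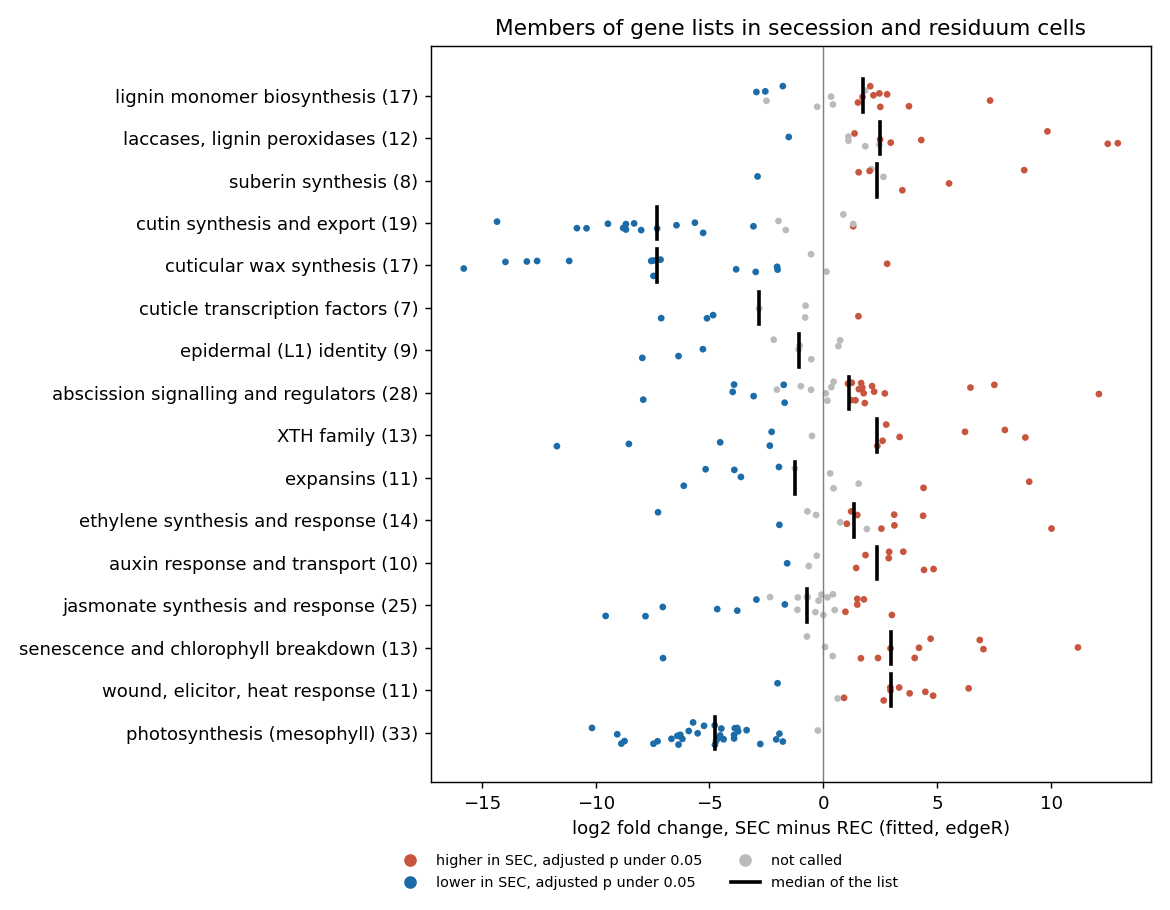
Fitted log2 fold change, SEC minus REC, of each tested member of 16 gene lists (points, spread vertically at random), with the number tested in brackets and black bars for medians; red and blue points had adjusted p under 0.05 and grey points did not. The medians of cutin and wax genes lie at -7.30 and -7.32 and that of photosynthesis genes at -4.76; fitted values of genes at 0 counts in a group are not bounds.

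Wall-loosening genes were mixed. Of 13 tested xyloglucan endotransglucosylase/hydrolase genes, 7 were higher in SEC, 5 lower and 1 not called (camera adjusted p = 0.428). XTH23 (AT4G25810) rose from 20.1 ± 7.18 to 1500 ± 184 CPM and XTH24 (AT4G30270) from 55.4 ± 8.3 to 376 ± 63.5 CPM, while XTH4 (AT2G06850) fell from 42.6 ± 8.8 to 0.0911 ± 0.158 CPM, a log2 fold change of -8.54. Without SEC replicate 2 it had 0 counts in SEC and was at least 324-fold lower. Of 11 tested expansin genes, 2 were higher, 5 lower and 4 not called (camera adjusted p = 0.582). EXPA1 (AT1G69530) rose from 86.0 ± 68.9 to 1810 ± 27.4 CPM, with a log2 fold change of 4.40 that was 5.30 without REC replicate 3, while EXPA4 (AT2G39700) and EXPA6 (AT2G28950) had log2 fold changes of -3.62 ± 0.35 and -6.13 ± 0.38 (SE). Of the 5 primary wall cellulose synthase genes, CESA1 (AT4G32410), CESA2 (AT4G39350) and CESA3 (AT5G05170) were lower in SEC, with log2 fold changes between -1.89 and -1.42, and the other two were not called (camera adjusted p = 0.241).

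**Figure D3:**
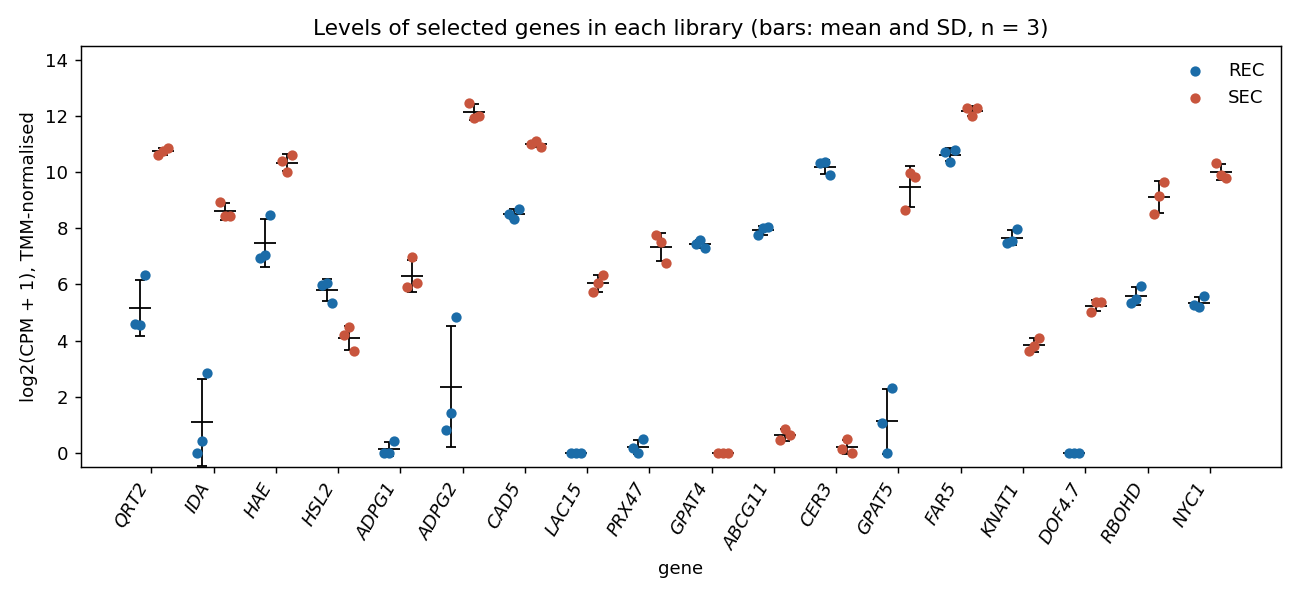
Level of 18 of the named genes, as log2(CPM + 1) with TMM scaling, in each REC (blue) and SEC (red) library; horizontal marks and bars give the mean and SD of 3 libraries. ADPG2 stood at 4570 CPM on average in SEC and 10.1 CPM in REC, and CER3 at 1190 CPM in REC and 0.166 CPM in SEC.

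Of the hormone lists only that of auxin passed. Of 10 tested auxin genes, 7 were higher in SEC, 1 lower and 2 not called (camera adjusted p = 0.0238; adjusted p = 0.614 with an estimated correlation), within a range of 0.00923 to 0.111 over the alternatives with the preset correlation. This call was lost with no filter on low counts (adjusted p = 0.111) and without REC replicate 1 (adjusted p = 0.0761). GH3.6 (AT5G54510) and GH3.5 (AT4G27260), which conjugate auxin to amino acids, rose from 809 ± 48.8 to 5920 ± 52.2 CPM and from 480 ± 35.0 to 3550 ± 571 CPM, and the response gene IAA2 (AT3G23030) from 26.0 ± 1.11 to 296 ± 71.6 CPM. Of 14 tested ethylene genes, 8 were higher, 2 lower and 4 not called (camera adjusted p = 0.0746). Among the alternatives of camera the list passed only without REC replicate 2 (adjusted p = 0.045) and with library size alone (adjusted p = 0.0396), within a range of 0.0396 to 0.149 with the preset correlation. The ACC synthase gene ACS2 (AT1G01480) and the F-box gene EBF2 (AT5G25350) were higher by log2 3.12 ± 0.36 and 2.55 ± 0.28 (SE). The ACC oxidase gene ACO1 (AT2G19590) had 685 counts over REC and 3 over SEC, a ratio of 162 (95% counting interval 55.2 to 787), and without SEC replicate 2, with 0 counts left in SEC, it was at least 101-fold lower. Of 25 tested jasmonate genes, 5 were higher, 7 lower and 13 not called (camera adjusted p = 0.607). JAZ1 (AT1G19180), a repressor of jasmonate responses, rose from 321 ± 107 to 2580 ± 292 CPM, and its relative JAZ9 (AT1G70700) fell from 291 ± 138 to 11.5 ± 4.22 CPM. The storage protein gene VSP2 (AT5G24770) fell from 1780 ± 809 to 2.31 ± 1.74 CPM, a log2 fold change of -9.56 that was -10.24 without SEC replicate 2. Of 12 tested genes of floral identity and boundaries, 3 were higher, 5 lower and 4 not called (camera adjusted p = 0.495). AP1 (AT1G69120) fell from 190 ± 21.6 to 4.22 ± 0.957 CPM, SEP2 (AT3G02310) from 261 ± 17.0 to 73.2 ± 3.4 CPM and PTL (AT5G03680) from 16.2 ± 4.92 to 0.148 ± 0.256 CPM. The log2 fold change of PTL was -6.77, or -6.17 without SEC replicate 2. Without SEC replicate 1 it had 0 counts in SEC and was at least 138-fold lower.

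Genes of senescence and chlorophyll breakdown were higher in SEC as a list. Of 13 tested, 9 were higher, 1 lower and 3 not called (camera adjusted p = 0.00848; adjusted p = 0.398 with an estimated correlation). The chlorophyll breakdown genes NYC1 (AT4G13250), PPH (AT5G13800) and SGR1 (AT4G22920) rose by log2 4.71 ± 0.26, 2.95 ± 0.21 and 2.40 ± 0.19 (SE). Of 33 tested photosynthesis genes, a list fixed as markers of mesophyll cells, 32 were lower in SEC and 1 was not called, with a median log2 fold change of -4.76 (camera adjusted p = 9.05e-10; adjusted p = 0.614 with an estimated correlation). REC replicate 2 was above both other REC libraries in 28 of these genes, with a median ratio of 1.54 to their mean, as noticed after values were seen; over all genes tested it was so in 29.3%. PSBO1 (AT5G66570) fell from 437 ± 33.9 to 17.8 ± 4.37 CPM and PSAF (AT1G31330) from 237 ± 60 to 11.3 ± 0.795 CPM. The family of cytosolic ribosomal proteins had 243 lower, 8 higher and 16 uncalled members of 267 tested, with a median log2 fold change of -3.72 (camera adjusted p = 2.47e-33; adjusted p = 0.298 with an estimated correlation). Of 13 tested cell cycle genes 4 were lower and 9 were not called (camera adjusted p = 0.428), among the lower ones the replication genes MCM5 (AT2G07690) and PCNA1 (AT1G07370), with log2 fold changes of -4.43 ± 0.40 and -4.82 ± 0.56 (SE).

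A list of genes that respond within minutes to hours to wounding, elicitors and heat, fixed as a sign of the stress of cell isolation, was higher in SEC beside the senescence genes. Of 11 tested, 9 were higher, 1 lower and 1 not called (camera adjusted p = 0.0076; adjusted p = 0.398 with an estimated correlation). Unequal stress of isolation and a difference between the cell types cannot be told apart here. That holds for this list and for any stress-responsive genes among the other calls. The zinc finger genes ZAT10 (AT1G27730) and ZAT12 (AT5G59820) rose from 59.3 ± 12.8 to 1320 ± 323 CPM and from 127 ± 32.8 to 978 ± 88.5 CPM. Of 3 tested defence genes, PR3 (AT3G12500) and PR4 (AT3G04720) were called higher in SEC (camera adjusted p = 0.428 for the list). PR3 was at 137 ± 200 against 1070 ± 54.0 CPM (log2 2.96 ± 1.07, SE; edgeR adjusted p = 0.0406). This call ended without REC replicate 1 (adjusted p = 0.0889), REC replicate 2 (0.0582), SEC replicate 1 (0.0754), SEC replicate 2 (0.0856) or SEC replicate 3 (0.0863) and with library size alone (0.0694), within a range of 1.65e-05 to 0.0889 over its alternatives. Without REC replicate 3 its log2 fold change was 5.65. PR4 stood at 2.06 ± 3.56 against 208 ± 63.3 CPM, and its log2 fold change of 6.66 was 6.06 without REC replicate 2. Without REC replicate 3, the only REC library with reads, it was at least 2420-fold higher.

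The phloem, guard cell, xylem, pollen and nectary lists had at most 4 tested genes each. Of 4 tested phloem genes only SWEET11 (AT3G48740), a sugar transporter gene, was called (camera adjusted p = 0.82 for the list). It had 0 counts in REC and was at least 135-fold higher in SEC, at 7.82 ± 8.81 CPM, or at least 49.7-fold higher without SEC replicate 1. The single tested guard cell gene, SDD1 (AT1G04110), was at 2.0 ± 0.353 CPM in SEC and at least 34.5-fold above REC. The single tested xylem gene, the metacaspase gene MC9 (AT5G04200), rose from 2.22 ± 2.02 to 694 ± 157 CPM, with a log2 fold change of 8.29 that was 7.70 without REC replicate 2 and 9.03 without REC replicate 3. Of 2 tested pollen genes PRF4 (AT4G29340) was higher by log2 2.12 ± 0.62 (SE; edgeR adjusted p = 0.0178). This call ended without SEC replicate 2 (adjusted p = 0.0757) and with library size alone (adjusted p = 0.0565), within a range of 0.00226 to 0.0757 over its alternatives. None of the 4 nectary genes had enough counts to be tested.

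Further genes on the less frequent side of a list, where that side had 1 to 3 called members, were chosen after their values were seen. Lower in SEC were the monomer genes 4CL2 (AT3G21240), CCR2 (AT1G80820) and COMT1 (AT5G54160), with log2 fold changes of -1.78, -2.94 and -2.55, that of CCR2 being -3.61 without SEC replicate 2. The libraries of the groups overlapped for 4CL2 (edgeR adjusted p = 0.0137). The peroxidase gene PRX17 (AT2G22420) was lower by a log2 fold change of -1.52, a call (edgeR adjusted p = 0.0184) that ended without REC replicate 1 (adjusted p = 0.0705), SEC replicate 1 (0.0501) or SEC replicate 2 (0.0632). Also lower were the superoxide dismutase gene MSD1 (AT3G10920, -1.52), the ethylene receptor gene ERS1 (AT2G40940, -1.93), the auxin transporter gene PIN4 (AT2G01420, -1.59) and the calmodulin-like gene TCH3 (AT2G41100, -2.01). WRKY53 (AT4G23810), a transcription factor gene of the senescence list, had a log2 fold change of -7.04 that was -7.72 without SEC replicate 3. Higher in SEC were the floral genes AP3 (AT3G54340), PI (AT5G20240) and SHP2 (AT2G42830), with log2 fold changes of 1.67, 0.90 and 1.71. The call of PI (edgeR adjusted p = 0.0095) ended without SEC replicate 2 (adjusted p = 0.0541) and with library size alone (adjusted p = 0.237). The expansin gene EXPA14 (AT5G56320) had 0 counts in REC and was at least 77-fold higher in SEC. CFL1 (AT2G33510), of the cuticle transcription factor list, was higher by a log2 fold change of 1.54 (edgeR adjusted p = 0.028). That call ended without REC replicate 2 (adjusted p = 0.0664), REC replicate 3 (0.0561), SEC replicate 2 (0.106) or SEC replicate 3 (0.0859), and with upper-quartile scaling (0.0582) or library size alone (0.132).

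No list call held with an estimated correlation, a version of camera that also takes its p from the few residual degrees of freedom of the 6 libraries. Adjusted over the list alone, counts were the same as those over all genes tested except for laccases and peroxidases (9 higher, 1 lower), abscission regulators (16 higher, 6 lower) and the class III peroxidase family (17 higher, 6 lower) among the lists above. Of the genes named above, QRT2, CYP98A3, PRX47, MYB58, ABCG11, CYP86A2, PMR6, CESA1, CESA3, EBF2, PR3, CCR2, SHP2, ERS1 and WRKY53 overlap a gene on the opposite strand, and CER1 with CER1L1 and FAR4 with FAR5 are neighbouring copies; copies of other genes were not searched for. The levels of these genes are uncertain to that extent.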

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

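The tests of REC replicate 3, those of QRT2, the test over the smaller set of nested genes and that of genomic DNA over protein-coding genes were chosen after the results were seen. The other tests in this part were chosen before.

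The counter's summary lines lie outside the comparisons of the report, and they held much signal: 47.16% to 49.29% of uniquely placed reads fell on no feature, and 6.86% to 11.83% of all records were placed at more than 1 site. Genomic DNA spread over the genome is argued against, since 35.3% to 45.7% of 21669 protein-coding nuclear genes of at least 1 kb lay below 0.1 times the density of the unassigned reads spread over the nuclear genome; over 3936 transposable element genes the median was 0 times it in every library, though reads of repeated sequence placed at more than 1 site were not counted there. Reads without strand counted with a strand rule could also leave many reads unassigned, and would give a gene nested in an exon of an opposite-strand gene about the density of its host (a ratio of 0.5 to 2), but over 63 such genes the median ratio was 0.579 with a 95% bootstrap interval of 0.278 to 1.05, which decides neither way. After that result was seen, the ratio was taken again over the 24 pairs whose deposited host span holds the nested gene, since the nesting came from another annotation, and it was 1.45 with an interval of 0.742 to 2.13, whose upper end lies above that range. Both intervals lie above the low ratio fixed beforehand as the sign against a strand rule, so neither test argues against it. A strand rule on reads without strand stays open, since neither interval lies within 0.5 to 2. No biological explanation was tested.

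REC replicate 3 stood closer to SEC than the other REC libraries did: of 546 genes at least 8-fold higher in SEC, chosen without it, 64.3% were above both other REC libraries, against 18.5% of 482 genes for REC replicate 1 and 33.1% of 511 for REC replicate 2. Lower depth is argued against by its total over genes of 14464710, against 13721261 and 14659524 in REC replicates 1 and 2. Over all records this library was the lowest, at 30432789 against 30592276 and 32694182. REC-high genes stood at a median ratio of 0.859 (95% bootstrap interval 0.83 to 0.889) to the other REC libraries. For REC replicates 1 and 2 the ratios were 1.11 and 0.955, but these were taken to means that include REC replicate 3. The ratio of 0.859 lies below the 0.9 set for a small admixture, a bound chosen after the results were seen. An admixture that small would not by itself lower these genes so far, but a larger one could. Genes nearly absent from the other REC libraries stood at median shares of 0.95% (43 genes under 0.2% of their SEC level) and 1.32% (65 genes under 0.5%), but the tests of a common share did not settle an admixture by themselves: 55.8% and 46.2% of these genes lay within 2-fold of the median, on either side of a bound of 50% and so dependent on the cutoff, and the 24.5% found over all 546 genes was under it but set aside after it was seen, since their median share, 1.95%, is below the upper quartile of REC replicate 2, 2.14%. Admixed SEC cells or their RNA should bring every abundant SEC transcript. Of the 546 genes 5, ZF14, MAN1, BRN2 (AT4G10350), ABCB9 and AT1G50590, had upper 95% counting limits over 4 times below 0.95% of their lowest SEC library. The lowest was 0.0404% for ZF14 (MAN1 and ABCB9 overlap a gene on the opposite strand and the other 3 do not). The rule of at least 3 genes over 4 times below was set after these values were seen. These 5 are the lowest of 546 genes, and the limits cover counting error only, not loss of transcripts during amplification. They lie below that share, but an admixture of SEC cells stays undecided. Cells of another composition and a biological shift of this library stay open and were not tested.

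QRT2, whose promoter drove the reporter, was far lower in REC than in SEC. The TMM factors are argued against as the whole cause, since the log2 fold change without them was 4.83. They lay between 0.814 and 1.24, too close together to make a difference of this size, so that outcome was clear beforehand. For SEC cells in the REC libraries as the source of all QRT2 reads there, the values did not decide. QRT2 stood at 1.34% of its SEC level in REC replicates 1 and 2. Of 38 genes as abundant in SEC and at least 8-fold higher there, 4 had upper 95% counting limits over 4 times below that share of their lowest SEC library. The lowest was ADPG2 at 0.0429%. These 4 lie below the share, but they are the lowest of 38, and the limits cover counting error only. The same rule, set after the values were seen, was used for REC replicate 3. Expression of QRT2 in the REC cells themselves, at a low level, stays open as a biological hypothesis and was not tested. The cells were sorted by fluorescence in plants with this reporter, so the sorting itself may set part of the difference, which was not tested either. QRT2 also overlaps a gene on the opposite strand, so some of its reads may belong to that gene.

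The 6 libraries can be split into 3 and 3 in 10 ways, so no share of splits under 0.05 can be reached. For genes, 1 split, the real one, gave as many as its 10477 calls, and the highest other split gave 0. For lists, 4 splits gave at least the 9 calls of the real split, and the highest other split gave 12. Each other split puts libraries of both groups on each side, so the difference between the groups adds to the spread within each side. The counts of these splits are therefore no measure of chance, and neither comparison counts for or against it.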

How the results depend on the processing

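Scaling by library size alone and leaving out genes that overlap an opposite-strand gene were chosen after seeing the data. Under every alternative the counts of higher and lower genes stayed within 1.5 times those reported, between 3521 (library size only) and 5791 (limma voom) higher and between 3949 (opposite-strand overlaps left out) and 6925 (library size only) lower, and 0 genes called in both the main test and an alternative changed direction. Of the 84 named genes, 81 kept their call and direction under each alternative that tested them and 84 their direction. The alternative without opposite-strand overlaps tested 73 of them, that of at least 10 CPM tested 77, and the others tested 84. MYB63 (0.0104), PR3 (0.0406) and PRF4 (0.0178) missed an adjusted p of 0.01. DESeq2 gave no adjusted p for 29 genes. Of the genes named after their values were seen, 4CL2 (0.0587) and CFL1 (0.0785) lost their calls with the replicate block. The replicate numbers were tested as a replicate block, which gave 4644 higher and 4871 lower genes; deviations of same-numbered libraries correlated at -0.022, -0.01 and -0.016, so the numbers give no sign of pairing.

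The number of called lists depended on the test. With an estimated correlation 0 lists were higher and 0 lower. That version uses the few residual degrees of freedom, and the estimates lay above the preset 0.01 for some called lists (0.77 for photosynthesis, 0.33 for auxin, 0.18 for ribosomal proteins) and below it for cutin (0.0067) and wax genes (0.0095), so a larger correlation did not end those calls. For the other called lists which of the 2 ended the call was not tested. With fry, which asks whether a list's genes move one way on balance and compares them with no other genes, 14 were higher and 9 lower. Leaving out single libraries gave 4 to 7 higher lists and 4 lower ones. Some uncalled lists changed direction, all with adjusted p far from the threshold, and the cause was not tested: with no filter lipid transfer proteins (0.81) and small heat shock proteins (0.888), with the replicate block small heat shock proteins (0.881), and with library size alone phloem genes (0.939). Without single libraries adjusted p ranged from 0.431 to 0.903 for Casparian strip genes, from 0.76 to 0.998 for phloem, from 0.565 to 0.998 for pectin lyase-like genes, from 0.583 to 0.97 for lipid transfer proteins and from 0.64 to 0.913 for small heat shock proteins.

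Depth limits the low genes: 3 counts over a group correspond to 0.058 CPM in REC and 0.0818 CPM in SEC, and folds given against 0 counts over a group of 3 libraries are bounds at these levels.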

Other observations

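The tests of families by shared symbol stem were chosen after seeing the data. Of 222 families with at least 8 tested genes, camera with the preset correlation called 49, 26 higher and 23 lower in SEC, and none of the values given here passed with an estimated correlation. With library size alone the families named here kept their direction. Higher in SEC were some families of transcription factors: of 17 tested genes named ANAC 10 were higher and 0 lower (adjusted p = 0.0064; 0.546 with an estimated correlation), of 50 named MYB 27 were higher and 5 lower (adjusted p = 0.00649; 0.546), of 51 named WRKY 25 were higher and 8 lower (adjusted p = 0.0167; 0.546), and of 9 named ZAT 8 were higher (adjusted p = 0.00828; 0.546). ZAT and WRKY each hold 2 genes of the wound and stress list. Other such families did not pass, among them ERF with 13 higher and 13 lower of 49 (adjusted p = 0.385), BHLH with 19 and 11 of 47 (0.283), DOF with 5 and 4 of 13 (0.511) and TCP with 2 and 3 of 13 (0.964), and transcription factors as a whole were not tested. Of 47 U-box genes named PUB 25 were higher and 5 lower (adjusted p = 0.00649; 0.576), and of 14 genes named PRA 11 were higher and 0 lower (adjusted p = 0.0082; 0.546).

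Beside the ribosomal proteins, further families were lower in SEC. Of 11 tested genes named CCT, subunits of the cytosolic chaperonin for the most part, 9 were lower and 1 higher (adjusted p = 0.00649; 0.546 with an estimated correlation), of 20 named TIM, mitochondrial import proteins, 13 were lower and 1 higher (adjusted p = 0.00703; 0.546), and of 9 tubulin genes named TUBB 6 were lower (adjusted p = 0.00649; 0.546). Of 9 histidine synthesis genes named HISN 8 were lower (adjusted p = 0.00927; 0.546).

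The remaining families fixed before the data were examined did not pass. Pectin lyase-like genes had 15 higher and 12 lower of 39 tested (camera adjusted p = 0.582; adjusted over the list alone 15 and 14), GDSL esterase genes 8 and 14 of 30 (0.428), lipid transfer protein genes 5 and 8 of 24 (0.673), pectin methylesterase and inhibitor genes 5 and 7 of 27 (0.428), and small heat shock protein genes 2 and 3 of 23 (0.883; adjusted over the list alone 1 and 2).

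REC replicate 2 was above both other REC libraries in 3 of 4 tested phloem genes, 28 of 33 photosynthesis genes and 17 of 25 jasmonate genes, lists compared here after values were seen, against 5054 of all 17246 genes tested (29.3%). Larger differences were singled out in 2 phloem genes, SUC2 and PP2-A1, the photosynthesis gene LHCB1.1 and the jasmonate gene LOX2. In REC replicates 1, 2 and 3, SUC2 (AT1G22710) was at 0.965, 11.4 and 0.882 CPM and PP2-A1 (AT4G19840), which overlaps a gene on the opposite strand, at 2.17, 16.6 and 0 CPM. LHCB1.1 (AT1G29920), with the neighbouring copies LHCB1.2 and LHCB1.3, was at 29, 179 and 14.8 CPM and LOX2 (AT3G45140) at 0, 15.4 and 0.353 CPM. Reads of mitochondrial genes were 1.13% to 1.52% of gene counts in REC and 0.55% to 0.79% in SEC. Those of chloroplast genes were 0.24%, 0.26% and 0.51% in REC replicates 1, 2 and 3, and so highest in replicate 3, and 0.06% to 0.13% in SEC.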
